A study of Mus musculus with 37 samples.

How the data were processed

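The series measured polyadenylated RNA by sequencing in mouse primordial germ cells (PGCs), the embryonic precursors of eggs and sperm. Per the labels' protocols, germ cells carrying a green fluorescent reporter driven by Oct4 were sorted from staged embryos, and the RNA was amplified before library preparation. The conditional knockout, called DCKO in the labels, combined a floxed Dnmt1 allele with a Blimp1-Cre driver that is active in germ cells. Dnmt1 is the enzyme that copies DNA methylation to the new strand at replication. The labels describe 37 samples, of which 25 had values here: 7 at E10.5 and 18 at E11.5. The 12 samples at E13.5 were not analysed here.

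The authors deposited 1 table per stage, each with 1 column per sample and 24318 genes, in RPKM, a read value scaled by transcript length and by the number of mapped reads. The submitters' processing notes name the mouse genome build mm9, TopHat2 version 2.1.0, Cufflinks version 2.2.1 and Cuffdiff, without saying which of them made these tables. The gene models, filters and gene lengths used are not given in the sources used here. The values show no steps of whole reads, so the depth of each library is unknown, and no counting interval or floor is given. The per-library sum of deposited RPKM ran from 669740 to 1121158 at E10.5 and from 516450 to 1027688 at E11.5. An exact 0 in such a table can be a failed estimate, which the values alone do not tell apart from absent or missed RNA. Of the 3491 genes with a median of at least 20 RPKM at E11.5, 104 were listed at 0 in some library. At E10.5 79 of 3595 were. Such genes are therefore described here as listed at 0, by library, with no fold. RPKM of microRNA and small nucleolar RNA genes rests on very short gene models. Genes with near-identical copies, such as the Xlr genes, can share reads, and their values are uncertain.

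Samples were grouped by the stage, sex and genotype in the labels. The labels do not say whether libraries of a group came from separate embryos. The p-values of single genes and of exact permutations therefore measure the spread between these samples, which may be technical in part. No pair of libraries was identical: the highest correlation of log2 values between libraries was 0.831 at E10.5 and 0.878 at E11.5. Each stage was tested within its own table, since the tables may have been normalized separately.

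Tests used limma version 3.58.1 in R version 4.3.3, with an intensity trend, on log2(RPKM + 1). Genes with a mean of at least 1 RPKM over the libraries of the table were tested, 11584 at E10.5 and 12667 at E11.5. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The E11.5 model held 4 group means (sex by genotype), and the genotype effect was the mean of the female and male differences. The E10.5 model had additive terms for genotype and sex, since only 1 male DCKO library was present. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Dnmt1, Dazl and the sex label genes were also tested by exact permutation of all splits of the libraries. All tests were two-sided, apart from the count of other splits.

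Before the data were examined, 21 gene lists were fixed: methylation-repressed germline genes, meiotic prophase, male germ cell differentiation, piRNA and transposon defence, both classes of imprinted genes, pluripotency, PGC identity, DNA methylation machinery, X-linked Rhox, Mage and Xlr families, p53 targets and apoptosis, proliferation, interferon response, gonadal somatic cells, mesenchyme, endothelium, erythroid cells, macrophages, gut epithelium, mitochondrially encoded genes and sex label genes. Lists with at least 3 tested members were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01. With this preset, camera's p rests mainly on the spread between genes. It allows little for members that vary together across libraries. The mitochondrially encoded genes were not found in either table under the symbols used, and that list was not tested.

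The genes named were also fixed by rule before the data were examined. For each genotype comparison these were Dnmt1, the 8 largest rises and 8 largest falls past the threshold, and up to 4 members of each list past the threshold, or the 1 with the smallest p where none passed. For the other comparisons they were the 4 largest rises and falls past the threshold, or the 2 genes with the smallest p; Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were added for the sex labels. Further list members with small p are named in places and were chosen after their values were seen.

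Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 RPKM. Also fixed then were median-of-ratios scaling, quantile normalization, library weights, other models and leaving out each library. So was a replicate block, by replicate number or by the number before the dash in the sample title (the title number). For lists the alternatives were camera with an estimated correlation and limma's fry. Alternatives chosen after seeing the data left out genes listed at 0 throughout 1 genotype or sex, the 3 E11.5 libraries highest in somatic markers, or the 2 libraries of each stage with the fewest genes at 1 RPKM or more. Others added the somatic marker mean as a covariate, tested list means per library by exact permutation, or joined both stages in 1 model.

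The code was tested on simulated data drawn from the real genes' means and spreads, with 200 changed genes. At E11.5, with 12667 genes, it recovered 5.97% of genes changed by 1 on the log2 scale, 49.3% of those changed by 2 and 89.4% of those changed by 3. At E10.5, with 11584 genes, it recovered 0% at each of these sizes. Thus a gene missing from the E10.5 calls says little about that gene.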

Results

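The data comprised RNA-sequencing profiles of sorted PGCs from DCKO and control embryos. At E10.5 there were 3 DCKO libraries (2 female, 1 male) and 4 control libraries (2 of each sex). At E11.5 there were 10 DCKO libraries (6 female, 4 male) and 8 control libraries (4 of each sex). The number of genes at 1 RPKM or more ran from 9125 to 11095 per library at E10.5 and from 8277 to 13200 at E11.5.

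Dnmt1, the targeted gene, was lower in every DCKO library than in every control library at both stages. At E11.5 it averaged 29.6 ± 16.3 RPKM in DCKO (SD, n = 10) and 130 ± 76.6 RPKM in control PGCs (SD, n = 8), with DCKO libraries reaching at most 59.4 RPKM and controls lying between 72.9 and 296 RPKM. At E10.5 it averaged 21.5 ± 7.43 RPKM in DCKO (SD, n = 3) and 90.9 ± 15.1 RPKM in controls (SD, n = 4), from 14.9 to 29.6 RPKM against 74.1 to 107 RPKM. The E11.5 log2 fold change was -2.07 (SE 0.34, limma adjusted p = 0.0355), and the exact permutation p for this gene alone was 4.6e-05 over 43758 splits. The E10.5 log2 fold change was also -2.07 (SE 0.38, limma adjusted p = 0.991), with an exact permutation p of 0.0286, the smallest that 35 splits can give. The tables give 1 value per gene, so RNA from an allele with deleted exons was not separated from intact RNA. The E11.5 adjusted p rested on single libraries: it lay above 0.05 when any of 12 of the 18 libraries was left out, with values up to 0.124, and under it only without female control 3, female DCKO 2, male control 1 or 2, or male DCKO 1 or 3. It also lay above 0.05 in 8 of 14 other settings, among them both replicate blocks, with values up to 0.908.

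**Figure D1:**
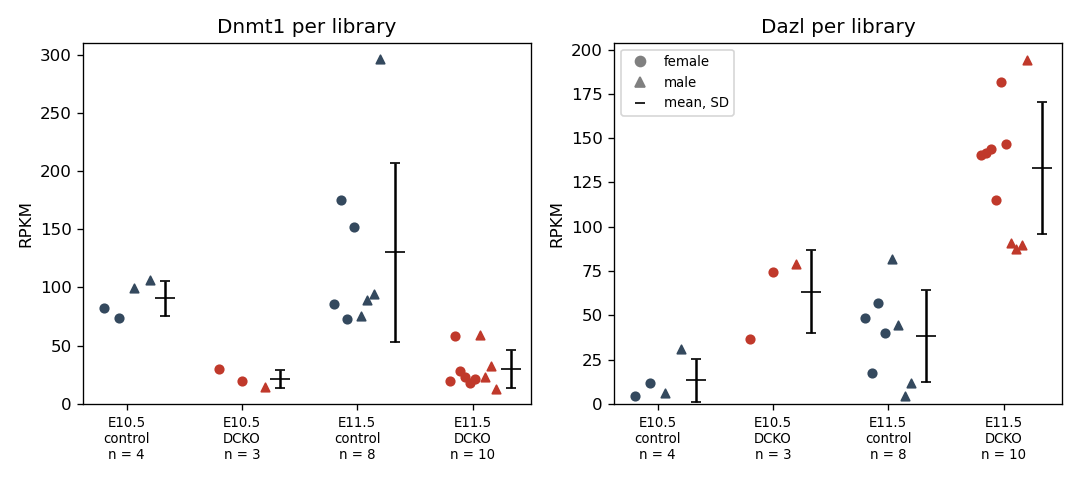
RPKM of Dnmt1 (left) and Dazl (right) in each library, by stage and genotype on the x axis; circles are female and triangles male libraries, and black marks give the mean and SD. DCKO libraries at E11.5 reach at most 59.4 RPKM for Dnmt1, under all 8 controls, and lie between 87.6 and 194 RPKM for Dazl, above all 8 controls.

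The E11.5 genotype comparison asked which genes differ in PGCs after deletion of Dnmt1. Dazl, an RNA-binding protein needed for germ cell development, had the smallest p among the methylation-repressed germline genes. It averaged 133 ± 37.4 RPKM in DCKO (SD, n = 10) and 38.3 ± 25.8 RPKM in control PGCs (SD, n = 8). All 10 DCKO libraries lay above all 8 controls (87.6 to 194 RPKM against 4.50 to 81.8 RPKM, exact permutation p = 2.3e-05, the smallest that 43758 splits can give). Permutation p of Dazl, here and below, are for this gene alone. They are not adjusted for its place as the list member with the smallest p. Dnmt1 fell, and Npm1 and Peak1 were listed at 0 in all 10 DCKO libraries.

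These 3 genes made up the calls, 0 up and 3 down, among 12667 genes (limma, Benjamini-Hochberg adjusted p). Without adjustment 692 genes had p under 0.05, 219 higher and 473 lower in DCKO. With no effect at all, a share of about 0.05 of the 12667 genes would have such a p. Counts of unadjusted p, here and below, therefore do not by themselves show changed genes. Npm1, an abundant nucleolar protein of ribosome assembly, ran from 2106 to 6115 RPKM in the 8 controls. Peak1, a pseudokinase linked to the cytoskeleton, ran from 2.18 to 34.9 RPKM in controls. At E10.5 Npm1 lay between 3308 and 5390 RPKM in the 3 DCKO libraries, and Peak1 was instead listed at 0 in all 4 controls and at 0.131 to 3.71 RPKM in DCKO. With such genes left out, 0 genes passed in limma, against 690 at an unadjusted p under 0.05, and the adjusted p of Dnmt1 was 0.106. Dazl had a log2 fold change of 2.08 (SE 0.41, limma adjusted p = 0.113), so it missed the threshold over all genes, and it passed without male control 1 (adjusted p = 0.0141). Without male control 1, or without male DCKO 3, 5 genes passed.

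Methylation-repressed germline genes, which DNA methylation holds silent in other cells, ranked higher in DCKO at E11.5. Of 26 tested members 24 had a log2 fold change above 0, with a median of 0.63 (camera adjusted p = 2.0e-08; adjusted p = 0.520 with an estimated correlation). Without male control 3 the median was 0.36 (camera adjusted p = 0.00562), and without male DCKO 1 it was 0.94 (4.0e-14). Male control 3 had the lowest mean log2 value of the list, 1.84 against 3.18 to 4.76 in the other controls and 2.96 to 5.12 in DCKO, the lowest mean of PGC identity genes, 3.50, and the highest mean of somatic markers, 4.17, of the 18 libraries. No member passed over all genes, and 1, Dazl, passed when adjusted over the list alone. Sohlh2, a transcription factor of early germ cells, had a log2 fold change of 1.27 (SE 0.41), and Ddx4, an RNA helicase of germ cells, of 0.94 (SE 0.40).

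The meiotic prophase and piRNA lists share 6 and 8 of their tested members with the germline list at both stages, among them Sycp3 and Smc1b with the first and Ddx4 and Asz1 with the second, so the 3 calls are not separate results. Meiotic prophase genes also ranked higher at E11.5, with 20 of 26 members above 0 and a median of 0.42 (camera adjusted p = 5.0e-04; adjusted p = 0.520 with an estimated correlation). Tex12, a part of the synaptonemal complex, had a log2 fold change of 2.30 (SE 0.62, limma adjusted p = 0.696), and was the 1 member that passed adjusted over the list alone. Without male control 3 the list call was lost (adjusted p = 0.0820). Genes of piRNA and transposon defence had 13 of 17 members above 0 and a median of 0.48 (camera adjusted p = 0.0034; adjusted p = 0.824 with an estimated correlation). That call was lost without male control 3 (adjusted p = 0.357, median 0.22), male DCKO 3 (0.0707, median 0.27) or male DCKO 4 (0.0532), and the median was 0.31 without female control 1 or male control 4. The macrophage list ranked lower, with 0 of 3 members above 0 and a median of -1.24 (camera adjusted p = 0.0034; adjusted p = 0.372 with an estimated correlation). Tyrobp, an adaptor of myeloid receptors, and C1qb, a complement component, had log2 fold changes of -1.66 (SE 0.51) and -1.24 (SE 0.44), and both passed adjusted over the list alone but not over all genes. Only 3 of the list's 12 genes were tested, at low and uneven levels. In controls Tyrobp averaged 4.91 ± 6.63 RPKM and C1qb 3.74 ± 6.81 RPKM (SD, n = 8). The list mean per library ran from 0 to 3.11 in controls and from 0 to 1.88 in DCKO on the log2 scale (exact permutation, adjusted p = 0.369).

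The other E11.5 lists did not pass camera's threshold. Imprinted genes silenced on the methylated allele had 14 of 25 members above 0, with a median of 0.15 and a mean of -0.02 (adjusted p = 0.860), and imprinted genes expressed from the methylated allele 12 of 16 (adjusted p = 0.221). PGC identity genes had 6 of 12 above 0 and a median of 0.02 (adjusted p = 0.949), and pluripotency genes 9 of 23 (adjusted p = 0.859). The DNA methylation machinery had 7 of 19 above 0 (adjusted p = 0.860), with Dnmt1 as its only member past the threshold. Rhox, Mage and Xlr genes had 11 of 19 (adjusted p = 0.170), p53 and apoptosis genes 10 of 20 (adjusted p = 0.536), and proliferation genes 10 of 26 (adjusted p = 0.860). Male germ cell differentiation had 7 of 9 (adjusted p = 0.536), interferon genes 2 of 6 (adjusted p = 0.860) and the sex label genes 4 of 5 (adjusted p = 0.531). Among markers of other cells, gonadal somatic cells had 1 of 10 above 0 (adjusted p = 0.860), mesenchyme 3 of 13 (0.532), endothelium 6 of 12 (0.859), erythroid cells 3 of 6 (0.905) and gut epithelium 4 of 6 (0.531). The median and the camera direction were opposite for interferon and erythroid genes, and the median and mean for PGC identity (mean -0.09). Leaving out 1 library brought some of these lists past the threshold. Rhox, Mage and Xlr genes passed without female control 2 (adjusted p = 0.0338), female DCKO 4 (0.0139), male control 1 (0.0294), male control 4 (0.00288), male DCKO 1 (7.2e-04) or male DCKO 4 (0.0259). Pluripotency genes (0.00532) and imprinted genes expressed from the methylated allele (0.0392) passed without male control 3, and male germ cell differentiation (0.0162) and mesenchyme (0.00863) without male DCKO 1. With other settings, Rhox, Mage and Xlr genes passed without the libraries with the fewest genes (0.00204), mesenchyme without those highest in somatic markers (0.0281) and imprinted genes expressed from the methylated allele with the somatic marker mean as a covariate (0.0402). The mean log2 value of 41 somatic markers ran from 0.61 to 4.17 over the E11.5 libraries, highest in male control 3, female DCKO 4 and male DCKO 1.

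Among the members with the smallest p of these lists, none passed over all genes apart from Dnmt1. Peg12, a paternally expressed imprinted gene, had a log2 fold change of -1.24 (SE 0.43), Esrrb, a pluripotency factor, of -1.02 (SE 0.67), and Cxcr4, a receptor that guides germ cell migration, of -1.06 (SE 0.50). Bcl2l11, a promoter of apoptosis, had a value of 1.08 (SE 0.44), Rrm2, a subunit of ribonucleotide reductase, of -0.59 (SE 0.25), and Fn1, a matrix protein, of -0.37 (SE 0.16).

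Within females at E11.5, Npm1 was the 1 gene past the threshold, listed at 0 in all 6 DCKO libraries and between 3410 and 6115 RPKM in the 4 controls. With genes at 0 in a whole group left out, 0 genes passed in limma, against 273 at an unadjusted p under 0.05. Dazl averaged 145 ± 21.4 RPKM in DCKO (SD, n = 6) and 40.9 ± 17.1 RPKM in control females (SD, n = 4; exact permutation p = 0.0048, the smallest that 210 splits can give).

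Within males at E11.5, Mrpl33, a protein of the mitochondrial ribosome, rose, and Ift43, a part of the transport machinery of cilia, fell. Mrpl33 averaged 913 ± 338 RPKM in DCKO (SD, n = 4) and 197 ± 64.8 RPKM in controls (SD, n = 4), a log2 fold change of 2.18 (SE 0.32, limma adjusted p = 0.0112). Ift43 averaged 0.566 ± 0.381 RPKM in DCKO (SD, n = 4) and 24.1 ± 18.3 RPKM in controls (SD, n = 4), a log2 fold change of -3.78 (SE 0.65, limma adjusted p = 0.0482). Npm1 and Peak1 were listed at 0 in all 4 male DCKO libraries, which brought the calls to 4, 1 up and 3 down. Dazl passed limma's threshold in neither sex. In males it averaged 115 ± 52.4 RPKM in DCKO (SD, n = 4) and 35.7 ± 35.3 RPKM in controls (SD, n = 4). Its exact permutation p in males was 0.0286, the smallest that 70 splits can give. The Mrpl33 call was lost without male control 2 (adjusted p = 0.0617), male control 3 (0.0668), male DCKO 2 (0.0566) or male DCKO 4 (0.0606), that of Peak1 without male control 3 (0.0771), male DCKO 2 (0.0566) or male DCKO 4 (0.0606), and that of Ift43 without 16 of the 18 libraries. The calls of Mrpl33, Ift43 and Peak1 were lost in a fit of the male libraries alone (adjusted p = 0.585, 0.585 and 1.00), without the libraries with the fewest genes (0.113, 0.280 and 0.113) and without those highest in somatic markers (0.260 for each). Mrpl33 was also lost with library weights (0.0820), and Ift43 with no filter (0.129), median-of-ratios scaling (0.0618), quantile normalization (0.254) and genes at 0 left out (0.0964). Either replicate block, by replicate number or by title number, also ended the calls of Mrpl33, Ift43 and Peak1.

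The effect of genotype was not shown to differ between the sexes. In limma's interaction test 0 genes passed, against 454 at an unadjusted p under 0.05. Gstm2 and Mrpl33 had the smallest p, with female minus male differences of 4.04 (SE 0.80, adjusted p = 0.932) and -1.98 (SE 0.44, adjusted p = 0.995) on the log2 scale.

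Between control females and males at E11.5, Eif2s3y, a translation factor gene on the Y chromosome, was the 1 gene past the threshold. It averaged 37.0 ± 23.2 RPKM in males (SD, n = 4) and 0.0253 ± 0.0183 RPKM in females (SD, n = 4), with a log2 fold change of -5.03 (SE 0.46, limma adjusted p = 2.3e-05). That call was lost with the title number as a block (limma adjusted p = 0.0616). Ddx3y, Kdm5d and Uty, also on the Y chromosome, had log2 fold changes of -2.09, -2.58 and -1.75, and Xist, which silences the X chromosome, of 2.08. None of these passed in the main fit. Apart from leaving out 1 library, Kdm5d passed in 2 of 11 other settings (lowest limma adjusted p = 3.4e-04) and Uty in 1 of 11 (0.0202). Over all 18 libraries each of the 4 Y genes gave an exact permutation p of 2.3e-05, the smallest that 43758 splits can give, and Xist gave 2.1e-04. Eif2s3y was at most 0.275 RPKM in the 10 female libraries and at least 19.4 RPKM in the 8 male libraries.

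At E10.5 Dazl again had the smallest p of the methylation-repressed germline genes. It averaged 63.2 ± 23.4 RPKM in DCKO (SD, n = 3) and 13.3 ± 12.2 RPKM in control PGCs (SD, n = 4), with all 3 DCKO libraries above all 4 controls. Its log2 fold change was 2.58 (SE 0.64, limma adjusted p = 0.991; exact permutation p = 0.0571). No gene passed in limma among 11584 tested, against 358 at an unadjusted p under 0.05, 173 higher and 185 lower in DCKO. Leaving out 1 library gave up to 11 calls, reached without male DCKO 1; it gave 4 calls without female DCKO 1, 4 without female DCKO 2, and 1 without either male control, and every one was a microRNA or small nucleolar RNA gene.

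The germline genes ranked higher as a list at E10.5 too, with 25 of 26 tested members above 0 and a median of 0.88 (camera adjusted p = 2.3e-07; adjusted p = 0.320 with an estimated correlation), or 0.55 without female control 1 (camera adjusted p = 1.7e-04). Of the 26 members tested at both stages, 23 had estimates above 0 at both. No member passed over all genes or adjusted over the list alone. Genes of piRNA and transposon defence had 13 of 16 members above 0 and a median of 1.12 (camera adjusted p = 5.8e-06; adjusted p = 0.281 with an estimated correlation). Gpat2, a membrane protein of piRNA formation, averaged 26.9 ± 20.8 RPKM in DCKO (SD, n = 3) and 3.88 ± 2.26 RPKM in controls (SD, n = 4). Meiotic prophase genes had 22 of 27 above 0 (camera adjusted p = 0.0055; adjusted p = 0.320 with an estimated correlation), and that call was lost without male DCKO 1 (adjusted p = 0.140).

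**Figure D2:**
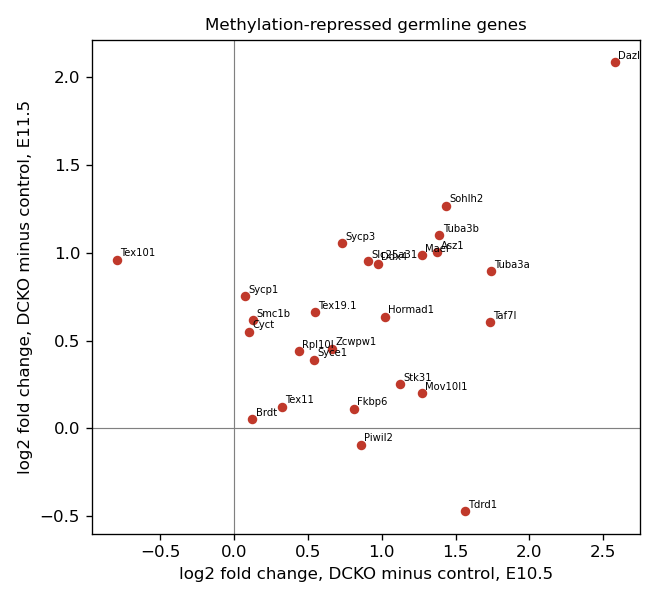
Log2 fold change, DCKO minus control, of each of the 26 methylation-repressed germline genes at E10.5 (x axis) and E11.5 (y axis); each point is 1 gene and the gray lines mark 0. Of the 26 genes, 23 lie above 0 at both stages, with Dazl farthest from 0 at 2.58 and 2.08.

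Pluripotency genes ranked lower in DCKO at E10.5, with 3 of 21 above 0 and a median of -0.40 (camera adjusted p = 0.0086; adjusted p = 0.368 with an estimated correlation). Tdgf1, a co-receptor for Nodal, averaged 4.72 ± 4.70 RPKM in DCKO (SD, n = 3) and 24.1 ± 18.7 RPKM in controls (SD, n = 4). That call was lost without female control 1 (adjusted p = 0.0923, median -0.25). It was also lost without the libraries with the fewest genes and with the title number as a block. Rhox, Mage and Xlr genes ranked higher, with 15 of 18 above 0 (camera adjusted p = 0.0174; adjusted p = 0.320 with an estimated correlation), as did p53 targets and apoptosis genes, with 14 of 20 (camera adjusted p = 0.0267; adjusted p = 0.540 with an estimated correlation). Plk2, a p53 target kinase, averaged 11.3 ± 3.65 RPKM in DCKO (SD, n = 3) and 3.02 ± 2.96 RPKM in controls (SD, n = 4). The Rhox, Mage and Xlr call was lost without female control 2 (adjusted p = 0.0539), female DCKO 2 (0.292) or male DCKO 1 (0.228), and the p53 call without female DCKO 1 (0.0891), male control 1 (0.0706) or male DCKO 1 (0.427). The first was also lost with a mean of at least 5 RPKM. The p53 call was also lost without the libraries with the fewest genes and with the title number as a block.

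Of the other lists at E10.5, imprinted genes silenced on the methylated allele had 11 of 24 above 0 (camera adjusted p = 0.707) and those expressed from it 6 of 14 (0.796). PGC identity had 5 of 11 (0.868), DNA methylation machinery 4 of 17 (0.266), male germ cell differentiation 5 of 9 (0.862), proliferation 7 of 26 (0.371), interferon response 1 of 6 (0.480) and sex label genes 4 of 4 (0.374). Gonadal somatic cells had 2 of 4 above 0 (0.868), mesenchyme 1 of 4 (0.757), endothelium 3 of 8 (0.796), erythroid cells 6 of 7 (0.796) and macrophages 0 of 4 (0.183). Median and mean had opposite signs for male germ cell differentiation, gonadal somatic cells, endothelium and erythroid cells. Gut epithelium, with 2 tested members, was not tested. No list at either stage passed limma's directional fry test. The DNA methylation machinery list, which holds Dnmt1 itself, passed limma's fry test of change in either direction at E10.5, at an adjusted p of 0.0011, and not at E11.5, at 0.697. Dnmt1 was its only member at E10.5 that passed adjusted over the list alone. Leaving out 1 library brought macrophages past camera's threshold without female control 1 (0.0474) or male control 1 (0.0193), and erythroid cells without female control 1 (0.0275). Macrophages also passed without the libraries with the fewest genes (0.0203) and with the title number as a block (0.0184).

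Imprinted Commd1 had a log2 fold change of -1.67 (SE 0.55) at E10.5 and of 0.63 (SE 0.38) at E11.5. Imprinted Peg10 had a log2 fold change of -1.49 (SE 0.55) at E10.5, and Top2a, a topoisomerase of dividing cells, of -0.58 (SE 0.33). None of these 3 genes passed at either stage.

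Between the sexes at E10.5, Eif2s3y averaged 45.5 ± 8.54 RPKM in males (SD, n = 3) and 0.0871 ± 0.0606 RPKM in females (SD, n = 4), with a log2 fold change of -5.44 (SE 0.57, limma adjusted p = 0.0393). Snord88a, a small nucleolar RNA gene, was listed at 0 in all 4 females and at 607, 782 and 1260 RPKM in the 3 males, and these were the 2 calls. With genes at 0 in a whole group left out, 0 genes passed in limma, against 415 at an unadjusted p under 0.05, and the adjusted p of Eif2s3y was 0.0787. The count was 1 without female control 2 and 6 without female DCKO 1. Without 1 library the adjusted p of Eif2s3y lay above 0.05 for every library but female DCKO 1, with values up to 0.302.

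Across the 11073 genes tested at both stages, the genotype effects correlated weakly, with Pearson's r of 0.0400 and Spearman's rho of 0.0833 across genes, which are not independent replicates. Without female DCKO 1 of E10.5 Pearson's r was -0.00724. In 1 model of both stages the effect differed for 1 gene, Npm1, listed at 0 in the E11.5 DCKO libraries alone, and 309 genes had an unadjusted p under 0.05. The Dazl effect differed by -0.47 between the stages (SE 0.84, adjusted p = 1.00).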

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

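Both tests of the Npm1 and Peak1 pattern were chosen or restated after their results were seen. Of 192 sets of values from 1 E11.5 group each, 20 held a library far from the others by Dixon's test, where chance gives about 1 in 20.

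The genotype effect on Npm1 differed between stages (limma adjusted p = 1.5e-16), because Npm1 was listed at 0 in the 10 E11.5 DCKO libraries and in none of the 3 E10.5 DCKO libraries. A loss of the transcripts from the germ cells would leave Npm1 above 0 wherever RNA of other dividing cells is present, yet it was at 0 in all 3 DCKO libraries among the 6 libraries highest in the somatic marker mean, a test first set on 1 library and widened to 3 after its values were seen. This argues against such a loss as the whole cause. Failed estimates in the authors' quantification may be the source, and stay open. Their test was restated to leave out short RNAs and genes at 0 in more than 9 libraries: 42 other genes were at 0 in 1 to 9 E11.5 libraries and at 100 RPKM or more in the rest, which meets the bound of at least 5 as first worded, but 40 were short RNA genes, and the 2 that remain decide nothing. The test also could not judge the pattern itself. It counted genes at 0 in part of the libraries, while Npm1 and Peak1 were at 0 throughout 1 genotype. Peak1, from 2.18 RPKM in the E11.5 controls, could not have met its limit of 100 RPKM.

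Dnmt1 was high in male control 4, at 296 RPKM against 75.9 to 94.8 RPKM in the other 3. Dazl was high in male DCKO 4, at 194 RPKM against 87.6 to 90.7 RPKM. The germline list mean was high in female control 1, at 4.50 on the log2 scale. Tex12 was high in male control 1, at 7.37 RPKM, as was Xlr5b, at 1.14 RPKM. Bcl2l11 was high in female DCKO 4, at 62.4 RPKM, and Tyrobp in female DCKO 3, at 1.82 RPKM, and in male DCKO 3, at 0.271 RPKM. The macrophage list mean was high in male DCKO 3, at 0.17, and the p53 list mean in male DCKO 4, at 4.43.

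Among markers of gonadal somatic cells, mesenchyme, endothelium and erythroid cells, male DCKO 1 was high in the means of the gonadal somatic (2.40), mesenchyme (4.67) and endothelium (3.56) lists. Female DCKO 4 was high in gonadal somatic cells (3.44) and low in pluripotency genes (4.36). Male control 3 was low in pluripotency genes (3.37) and high in erythroid genes (6.42), with Hba-x at 1470 RPKM. Female control 4 was high in erythroid genes (3.29), with Hba-x at 230 RPKM. These flags compare each library only with its own group. Over the E11.5 DCKO libraries, with no erythroid flag, the erythroid mean ran from 0 to 6.35 and Hba-x from 0 to 908 RPKM. High erythroid RNA was thus not confined to controls.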

How the results depend on the processing

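Settings that left out genes at 0 in a whole group, or doubted libraries, used the somatic covariate, or permuted list means were chosen after seeing the data. Unless a value or the setting's construction shows it, the cause of a shift was not tested.

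The count of genes for DCKO against control at E11.5, 3, became 5 with library weights and 0 without genes at 0 in a whole group, and ran from 2 to 5 leaving out 1 library. The female count, 1, became 2 with a pseudocount of 0.1, with no filter and with females alone, 4 with library weights and 0 without genes at 0 (range 1 to 2). The male count, 4, became 1 without genes at 0, without the libraries with the fewest genes and without those highest in somatic markers, and 8 with the somatic covariate (range 1 to 4). The interaction count, 0, ran from 0 to 1. The count between control sexes, 1, became 22 with library weights and 2 with no filter and without either set of doubted libraries (range 1 to 2). At E10.5 the genotype count, 0, became 5 without the libraries with the fewest genes and 7 for the female difference alone (range 0 to 11). The E10.5 sex count, 2, became 1 with no filter or a mean of at least 5 RPKM, 0 without genes at 0, and 7 without the libraries with the fewest genes (range 1 to 6). Leaving out male control 2 gave 2 genes for females, 2 for males, 1 for the interaction and 2 between control sexes; leaving out female DCKO 1 gave 2 for females; and leaving out male control 3, male DCKO 2 or male DCKO 4 gave 1 for males.

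The Dnmt1 log2 fold change at E11.5 stayed negative and missed the threshold with no filter (-2.07, adjusted p = 0.105), median-of-ratios scaling (-2.02, 0.0569), genes at 0 left out (-2.07, 0.106), fewest-gene libraries left out (-1.68, 0.121), somatic-marker libraries left out (-2.29, 0.0538) and the covariate (-2.08, 0.0574). More genes tested (no filter) and fewer small p ranked above it (genes at 0 left out) account for those, since its own p was nearly the same. Leaving out 1 library gave -2.25 to -1.85 at E11.5 and -2.31 to -1.65 at E10.5.

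Of the 4 lists past the threshold at E11.5, 0 remained past it with an estimated correlation, fry or permuted list means, and 2 lists passed with a mean of at least 5 RPKM, the piRNA list being lost at an adjusted p of 0.0502 (range 3 to 7). Of the 6 at E10.5, 0 remained with an estimated correlation, fry or permuted list means (range 3 to 7). Permuted list means had little room to pass at E10.5, so their result there decides nothing. Over 35 splits the smallest possible exact permutation p was 0.0286, and no list could pass by itself once adjusted over the lists. The Rhox, Mage and Xlr call was also lost with a mean of at least 5 RPKM (adjusted p = 0.351), and those of pluripotency (0.186) and p53 genes (0.237) without the libraries with the fewest genes. Without male DCKO 1, 7 lists passed at E11.5 and 3 at E10.5. The correlation between stages ran from -0.00724 to 0.0692 leaving out 1 E10.5 library. Hba-x at E11.5 changed sign, to 0.27 with the title number block and to 0.08 and 0.21 without female control 4 or male control 3 (range -1.54 to 0.21). Hbb-bh1 at E10.5 changed sign to 0.25 without female control 1 (range -3.36 to 0.25). Neither gene passed in any of these. Apart from leaving out 1 library, single lists kept their direction and side of the threshold in 382 cases, lost it in 36 and gained it in 5, and named genes in 659, 28 and 3. Most cases kept were lists or genes not past the threshold in the main fit, which had no call to lose. Among the calls, E10.5 pluripotency and p53 genes were each lost in 5 of 10 settings, and Ift43 in males in 9 of 14. The germline list was lost in 3 of 12 at E11.5 and 3 of 10 at E10.5, and Npm1 at E11.5 in 0 of 13. The 5 gains were Rhox, Mage and Xlr genes at E11.5 (adjusted p = 0.00204) and macrophages at E10.5 (0.0203) without the libraries with the fewest genes, mesenchyme at E11.5 without those highest in somatic markers (0.0281), imprinted genes expressed from the methylated allele at E11.5 with the somatic covariate (0.0402) and macrophages at E10.5 with the title number block (0.0184).

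Replicate numbers did not pair the libraries: same-numbered libraries of 1 sex had correlations of -0.165 to 0.150 at E11.5, 2 of 8 above 0.1. Title numbers gave -0.0229 to 0.490, with 6 of 13 pairs above 0.1, and 11 of 16 libraries correlated best with a library of their own number, a hint from the data. With the replicate block by replicate number the E11.5 counts were 2 for females, 2 for males and 2 for the interaction, and the Dnmt1 log2 fold change was -1.98 (adjusted p = 0.908); Mrpl33, Ift43 and Peak1 in males had adjusted p of 0.112, 0.397 and 0.393, and Peak1 over both sexes 0.171. With the title number as replicate block they were 1 for males and 0 between control sexes, 1 between sexes at E10.5, and -2.31 for Dnmt1 (adjusted p = 0.0729), with an adjusted p of 0.386 for both Mrpl33 and Ift43 and 0.331 for Peak1 in males, and of 0.0622 for pluripotency and 0.121 for p53 genes at E10.5. Depth is unknown, so what it limits cannot be stated per library.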

Other observations

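The tests of list means against germ cell share and of residual Dnmt1 were fixed before their results were seen; those with the somatic covariate and the imprinted genes, and the list means without each library, were chosen after.

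Some genes outside the rule, chosen after their values were seen, differed at E10.5 in the group means without passing limma's threshold. Bax, an effector of apoptosis, averaged 86.4 ± 2.88 RPKM in DCKO (SD, n = 3) and 44.2 ± 18.8 RPKM in controls (SD, n = 4). Stag3, a meiotic cohesin, averaged 66.6 ± 14.3 RPKM in DCKO (SD, n = 3) and 34.3 ± 11.3 RPKM in controls (SD, n = 4). Gadd45a, a p53 target, was instead lower in the mean, at 9.26 ± 9.47 RPKM in DCKO (SD, n = 3) and 22.9 ± 2.87 RPKM in controls (SD, n = 4).

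The germline list ranked higher in DCKO at both stages. A larger share of germ cells in the DCKO libraries would raise PGC identity genes alike, yet the germline mean minus the PGC identity mean was higher in DCKO at E11.5 by 0.71 on the log2 scale (exact permutation p = 0.0218, n = 10 and 8), though by 0.53 without male control 4 (exact permutation p = 0.0529), and at E10.5 the difference missed the threshold (exact permutation p = 0.229), which leaves that explanation open there. With the somatic marker mean as a covariate the E11.5 list median was 0.56 against 0.63 without, which argues against fewer somatic cells as the whole cause, but 0.30 against 0.58 without male control 4, so a part in it stays open. An effect of the deletion on genes silenced by methylation may account for the pattern and stays open: imprinted genes silenced on the methylated allele differed by 0.0325 (exact permutation p = 0.927), which decides nothing.

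The germline list's own mean per library differed by 0.66 at E11.5 (exact permutation p = 0.0978) and by 0.88 at E10.5 (exact permutation p = 0.114), so the pattern is not established across libraries. Single libraries moved the E11.5 difference: it was 0.37 without male control 3 (exact permutation p = 0.237), the library lowest in this list and in PGC identity genes and highest in somatic markers, and 0.83 without male DCKO 1 (exact permutation p = 0.00934), the only library whose omission brought p under the threshold.

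The Dnmt1 RNA left in the 10 E11.5 DCKO libraries may come from other cells. Its log2 value had a Pearson's r of 0.458 with the somatic marker mean (permutation p = 0.168) and a Spearman's rho of 0.467 (permutation p = 0.181), the 1 relation tested. Without the 2 libraries farthest from the median r was 0.506. With 10 libraries this cannot be told apart from no relation, and RNA from the deleted allele stays open and untested.

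Other splits of the same libraries were tested for each comparison, and each count of splits below includes the real one. For DCKO against control at E11.5, 2 of 100 splits within sex gave at least 3 genes, the highest other split giving 3. The count includes 2 genes listed at 0 throughout DCKO and was 0 without such genes. The split test therefore says nothing beyond that pattern of zeros. For females 4 of 100 splits gave at least 1 gene (highest other 2). The 1 gene called was Npm1, listed at 0 in all 6 DCKO libraries, and without such genes the count was 0. That test too says nothing beyond the zeros of Npm1. For males 2 of 35 splits gave at least 4 genes, the real split and 1 that gave 57. The latter points to a structure of the male libraries whose source was not tested, and chance cannot be excluded. Chance cannot be excluded for the count between control sexes either (3 of 35 at 1 or more, highest other 1). That concerns the count and not its 1 gene, Eif2s3y. Over all E11.5 libraries this gene was at most 0.275 RPKM in the 10 female and at least 19.4 RPKM in the 8 male libraries. For the interaction the count was 0, so all 100 of 100 splits gave as many and the test says nothing about chance (highest other 5). The same holds for genotype at E10.5, where all 34 splits that could be fitted gave 0 or more genes. The highest other count came from female controls 1 and 2 with female DCKO 2 against the rest. With sex in the model, that split set female DCKO 1 alone against the other females, so it reflects that 1 library. Female DCKO 1 was among the libraries with the fewest genes and had a library weight of 0.251. For sex at E10.5, 17 of 34 splits gave at least 2 genes (highest other 18), and chance cannot be excluded for that count. For the lists, 55 of 100 splits at E11.5 gave at least 4 lists (highest other 15) and 3 of 34 at E10.5 gave at least 6 (highest other 6), so chance cannot be excluded for either count of lists.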
